A study of Mus musculus with 6 samples.

How the data were processed

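RNA from 6 pools of Ter119-positive fetal liver cells was labelled with biotin and hybridised to Affymetrix Mouse430_2 arrays, 1 pool to an array, per the labels' protocols and the series design text. Groups and replicate numbers came from the sample titles: 3 wild type and 3 STAT5 knockout pools, each of 3 to 5 embryos, so that replicates are separate pools of animals. The deposited table holds 1 value per probe set and array, an intensity on a linear scale. The submitters' processing notes name RMA and Partek, with no version. The values fit standard RMA poorly, since they are linear and the arrays' quantiles are unequal. Each array has a mean of 500 after 2% of values are left out at each end, which is a scaling of single arrays. How that scaling was made is not given in the sources used here. The design text adds that the submitters chose genes by ANOVA in Partek at p under 0.05 and over 1.5-fold. Because the table is linear, log2 of the deposited intensity was used with no pseudocount (no value was 0 or below). The alternatives were set on the same values.

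Probe sets were named from the GEO platform annotation. Of 45037 probe sets other than 64 control probe sets, 34945 had 1 gene symbol, 932 several and 9160 none in that table. Those with several or none entered the probe set tests but not the gene tests. Symbols were looked up by Entrez ID in a RefSeq gene table of the assembly GRCm38.p6, where 34741 matched and 0 symbols changed. The files name no genome build, so no coordinates are given. A gene was represented by its probe set with the highest mean log2 signal over the 6 arrays, which gave 18193 genes. Fits without 1 array chose that probe set again on the arrays left. Of the 95 named genes, 55 have several probe sets. For 8 of these, Socs2, Myoz1, Zfp369, Slc44a1, Dpys, Hbb-y, Cbfa2t3 and Aurkb, the probe sets gave both directions.

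The main test was limma's lmFit and eBayes on log2 signal of all 6 arrays, knockout against wild type, with Benjamini-Hochberg adjustment and a threshold of 0.05, and no filter on dim probe sets. The same model with a mean-variance trend (eBayes with trend) was fixed as an alternative before the data were examined. It is given beside the main test because dim probe sets vary more than bright ones here. The 30 gene lists and 14 single genes were also fixed at that point. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. In the list tests p-values were adjusted over 30 lists. The ANOVA of the submitters' criterion, which with 2 groups equals the methods' t-test, was run on the same values. As detection calls are not used here, the 95th percentile of 27 control probe sets for Bacillus subtilis transcripts, over all arrays, served as the level of background. For a gene whose dimmer group has a mean under that level, only "at least N-fold" is given. Its dim values are raised to the level first, and both groups' measured means are kept in the tables. No fold is given where both are under it. Scaling shifts the median difference of all genes by over 0.1 between settings: it was -0.08 on the deposited scale, -0.04 after quantile normalization and 0.03 after median centring, and differences are to be read against these.

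The rule for named genes took all Stat5a and Stat5b probe sets and the 12 largest rises and 12 largest falls past the threshold with non-overlapping groups. From each list it took up to 4 members past the threshold or, if fewer than 2 passed, the 2 with the smallest p, given as values, and it always took the fixed genes. As the main test called 8 genes, the same number of rises and falls of the fit with the trend, with the brighter group above the control level, was added after the data were examined. Genes called with the trend outside this rule, further examples from the lists, and Podxl, Tnfrsf13c and Spred2 were chosen after their values were seen.

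Alternatives tried were the trend, the trend with robust estimation, the t-test with adjustment, quantile normalization, median centring, leaving out the 50% of probe sets with the lowest mean, array weights, the replicate number as a block, leaving out each array in turn, adding 32 to the linear value, the mean of all probe sets of a gene, and leaving out probe sets whose names end in _x_at, _s_at or _a_at. For lists they were the other set tests and leaving out the 20 genes held by over 1 list. Scripts were tested on simulated data with the real genes' means. Spreads were drawn around the trend of spread with brightness, which is what the fit with the trend assumes, and noise was independent between genes. Of 100 genes changed by 2 on the log2 scale the main test recovered 11% and the fit with the trend 48%, and of 100 changed by 1 they recovered 0% and 15%. False calls among the other genes numbered 1 and 6. Camera called 10 of 10 simulated lists shifted by 0.5 and 0 of 10 others. Members of the real lists are correlated (median estimated correlation 0.15), so this result does not carry over to them. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.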

Results

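The data are 6 expression arrays of RNA from Ter119-positive fetal liver cells of mouse embryos at embryonic day 14.5. Ter119 is a surface antigen of maturing red blood cell precursors, and the fetal liver is the main site of red cell production at this stage. Cells of 3 to 5 embryos of 1 genotype were combined in each pool, with 3 wild type pools and 3 STAT5 knockout pools. STAT5A and STAT5B are transcription factors that the erythropoietin receptor activates through the kinase JAK2. The comparison asks which transcripts of erythroid cells differ when both are missing. The deposited values are linear intensities of 45101 probe sets, called signals here. The median signal of an array lay between 175.6 and 215.8, and the 3′ to 5′ signal ratio of the actin control probe sets between 0.965 and 1.04. Between 41.0% and 49.3% of the probe sets of an array were dimmer than the 95th percentile of its control probe sets for Bacillus subtilis transcripts, which mouse RNA lacks. Over all arrays that percentile was a signal of 162.5, and it is called the control level below. Groups of 3 arrays limit the precision, and the smallest two-sided p of an exact permutation test with 3 against 3 is 0.1. Differences are given as log2 signal in knockout minus log2 signal in wild type, with the standard error (SE) of limma's fit without a mean-variance trend. Levels are mean log2 signal ± SD, with n = 3 per genotype.

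The targeted genes were measured first, as a check on the labels. The brighter probe set of Stat5a read 8.54 ± 0.15 in wild type and 7.10 ± 0.17 in knockout pools. The dimmer Stat5a probe set read 7.76 ± 0.35 and 3.99 ± 2.19. For Stat5b, the first probe set read 9.09 ± 0.09 and 7.79 ± 0.54, and the second 9.13 ± 0.33 and 6.59 ± 0.98. With all 4 probe sets, each knockout array lay below each wild type array. The knockout means of 3 of them lay under the control level, so wild type was at least 2.29-fold and at least 1.33-fold higher for Stat5a and at least 3.45-fold higher at the second Stat5b probe set. The first Stat5b probe set stayed above that level in knockout pools, 2.45-fold under wild type. Where the deleted part of either gene lies against these probe sets is not given in the sources used here, and a probe set outside it checks nothing. None of the 4 passed an adjusted p of 0.05 among 45037 probe sets (adjusted p between 0.237 and 0.532, limma).

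**Figure D1:**
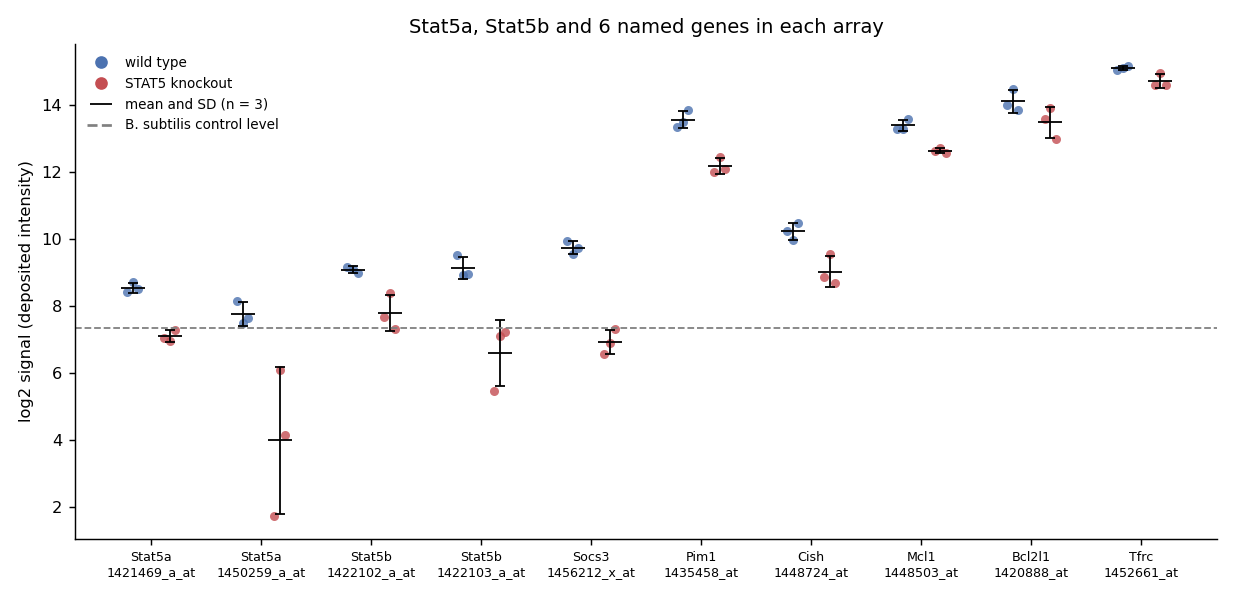
Log2 signal (y axis) of each array for the 4 Stat5a and Stat5b probe sets and 6 named genes (x axis), with wild type in blue, STAT5 knockout in red, black bars for the mean and SD of 3 arrays and a dashed line at the control level of 7.34. All 3 knockout arrays lie below all 3 wild type arrays for every item shown except Bcl2l1, whose groups overlap at the probe set shown.

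Of 21 measured target genes of cytokine-STAT5 signalling 15 were lower in knockout pools, 8 of them without overlap of the groups, where the median of all genes was -0.08. Markers of hepatocytes and endothelium, treated below, were lower as well. Socs3, which encodes a feedback inhibitor of cytokine receptors, went from 9.74 ± 0.20 to 6.92 ± 0.36, at least 5.27-fold lower. Pim1, a kinase that promotes survival, went from 13.57 ± 0.25 to 12.17 ± 0.24, a difference of -1.40 (SE 0.23). Cish, another feedback inhibitor, differed by -1.20 (SE 0.30), and Mcl1, an anti-apoptotic BCL2 family member, by -0.76 (SE 0.18). Bcl2l1, the anti-apoptotic gene of late erythroid cells, differed by -0.62 (SE 0.31) with overlapping groups at its brightest probe set, and by -0.37 without knockout replicate 3. Its other probe sets differed by -0.29, -0.37 and -0.63, and only at the last did the groups not overlap. Socs2 differed by -0.57 and Osm by -0.51, each with all knockout arrays below all wild type arrays. Adjusted over the list alone, 8 of the 21 measured members of the cytokine-STAT5 list passed the threshold. Of these, 6 fell, Socs3, Pim1, Cish, Mcl1, Podxl and Tnfrsf13c, and 2 rose, Spred2 and Myc. Over all genes tested none passed in the fit without a trend (Socs3 had an adjusted p of 0.0536). With a mean-variance trend Socs3 (adjusted p = 0.0058) and Pim1 (0.0111) fell and Spred2 (0.0314) rose. The list as a whole was called lower by fry's directional test (adjusted p = 0.0096, median -0.18), the only list of 30 that this test called. It was not called by camera (adjusted p = 0.175, and 0.839 with an estimated correlation). The fry call ended with the replicate number as a block (adjusted p = 0.267) and after median centring (0.330, median -0.064). It also ended without wild type replicate 1 (0.0723), 2 (0.148) or 3 (0.103) and without knockout replicate 3 (0.0622). The median moved to -0.37 without knockout replicate 3, -0.091 without knockout replicate 1, -0.052 without knockout replicate 2 and -0.40 with the mean of all probe sets.

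Among the 14 genes fixed by name before the data were examined, 5 passed adjusted over the list alone, Stat5a, Stat5b, Socs3, Pim1 and Cish. Over all genes tested none passed in the fit without a trend, and Socs3 and Pim1 passed with it. Tfrc, the transferrin receptor through which erythroid cells take up iron, differed by -0.38 (SE 0.18) at its brightest probe set, 15.10 ± 0.05 against 14.72 ± 0.20. Its other probe sets gave -0.49 and -0.50, and 3 control probe sets for the same transcript, not used in any fit, between -0.61 and -0.47. With all 6, every knockout array lay below every wild type array, but Tfrc did not pass over the list alone (adjusted p = 0.147, limma). Ireb2, a regulator of Tfrc mRNA, differed by -0.02 (SE 0.19). The erythroid transcription factor genes Gata1 and Klf1 differed by -0.14 and -0.01, and the erythropoietin receptor gene Epor by 0.28 (0.18 without wild type replicate 2). Without 1 array the values of Gata1 ran from -0.28 to -0.010. Alas2, which encodes the first enzyme of heme synthesis, read between 80.7% and 93.3% of each array's highest signal, close to the ceiling, so its difference of -0.16 does not show whether the transcript changed. The differences of Ireb2 and Klf1 turn sign after median centring, and that of Alas2 after quantile normalization.

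Over all 18193 genes, large rises in knockout pools were those of C1qtnf12, Aqp1, Hspa1a and Slc44a1, and large falls those of Socs3, Tnfrsf21, Ston2, Noct and Cd36. These genes passed in limma's fit with a mean-variance trend, and were chosen after their values were seen. Aqp1, the water channel of red cells and vessels, rose by 2.52 (SE 0.27), from 11.31 ± 0.17 to 13.83 ± 0.44. C1qtnf12, a secreted hormone-like protein, rose by 2.89 (SE 0.49), and Slc44a1, a choline transporter, by 2.07 (SE 0.19). Of the 4 probe sets of Slc44a1, 2 were lower in knockout pools, by up to -1.55, and 1 of these 2 lay above the control level in at least 1 genotype. Cd36, a fatty acid receptor of early erythroblasts, fell by 1.68 (SE 0.19), from 12.29 ± 0.16 to 10.61 ± 0.18. Dnaja4, a heat shock protein 40 co-chaperone, fell by 1.26 (SE 0.16), and Noct, a circadian regulated phosphatase, by 1.71. Gas5, a growth arrest-associated non-coding RNA gene, rose by 1.18 (SE 0.16). Other genes among the 12 largest rises were Zfp369, Fgf13, Ndrg2, Soga1, Ugcg, Adcy7 and Lpin1. Further falls that ended under the control level were those of Apol11b (at least 8.41-fold), 1810053B23Rik, Trmt61a, Adh6b and Dpys. The probe sets of Zfp369 and Dpys gave both directions, but the opposing probe sets of these genes lay below the control level in both genotypes. The fit called 80 genes, 44 higher and 36 lower in knockout, of which 67 lay above the control level in both genotypes. Median centring gave 29 higher and 13 lower, and the mean of all probe sets of a gene 13 higher and 23 lower, so that the larger direction depends on the setting. The count fell to 22 without wild type replicate 1, 29 without wild type replicate 2, 9 without knockout replicate 1, 34 without knockout replicate 2 and 11 without knockout replicate 3. In all 6 of these fits, with the one without wild type replicate 3 included, 7 genes were called: Socs3, Cd36, Dnaja4 and Ston2, lower, and Aqp1, Gas5 and Slc44a1, higher. With the replicate number as a block 58 of the 80 kept the call, these 7 included, and 22 lost it. Among the 22 were Trp53inp1, Gss, Plin3, Trmt61a, Adh6b and Dpys. Of the 80, 27 were called in none of the 6 fits without 1 array, among them the genes just named and Hspa1a.

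The fit fixed as the main test, without the trend, called 8 genes, 2 higher and 6 lower. Abtb2 rose by 2.16 (SE 0.17), from 7.35 ± 0.13 to 9.51 ± 0.05, with both groups above the control level. Ppm1e, Plpp4, Cks1brt and Myoz1 fell to below the control level, so wild type was at least 1.50-fold, at least 1.13-fold, at least 1.70-fold and at least 3.88-fold higher. Rab20, called higher, and Ube2u and Tnmd, called lower, lay below that level in both genotypes and get no fold. Of the 8, 5 were also called with the trend. At an unadjusted p under 0.05 there were 1620 genes. The count was 4 by the methods' t-test after adjustment, 15 after quantile normalization (6 higher and 9 lower) 0 with the replicate number as a block and 0 without any 1 of the 6 arrays. Groups did not overlap for 16.9% of genes, where chance gives 10%.

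**Figure D2:**
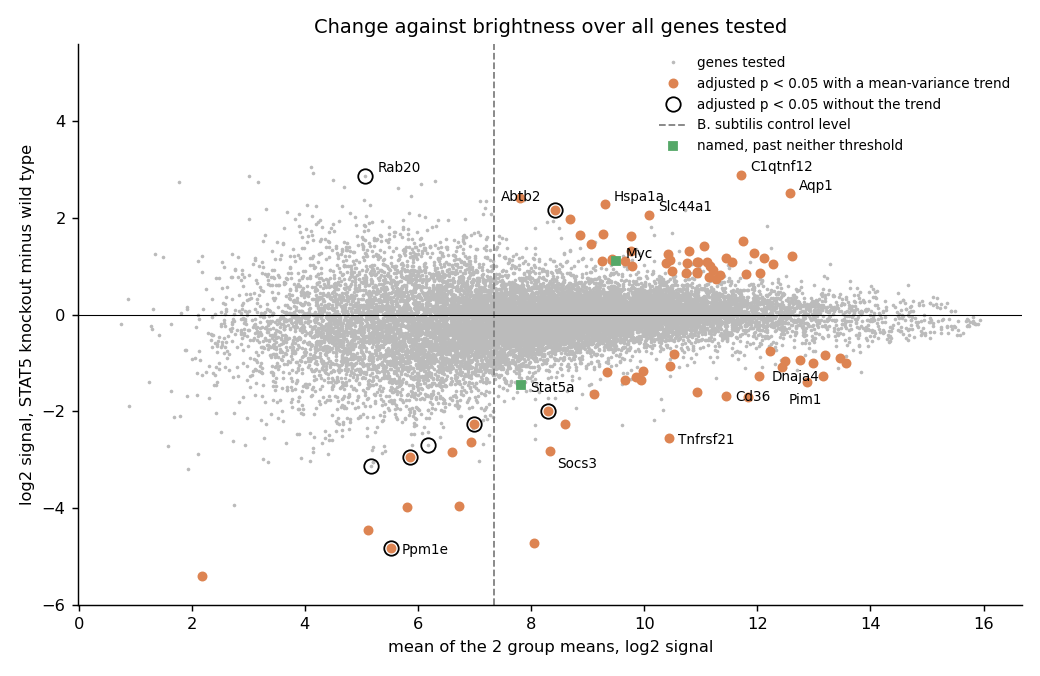
Difference in log2 signal, STAT5 knockout minus wild type (y axis), against the mean of both group means (x axis) for each of 18193 genes, with the 80 genes called with a mean-variance trend in orange, the 8 called without it ringed and Stat5a and Myc, past neither threshold, as green squares. Differences spread more widely left of the dashed control level at 7.34, and 67 of the orange genes lie above it in both genotypes.

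The submitters' own criterion, a p under 0.05 without adjustment and a fold over 1.5, was met by 2337 of 45037 probe sets, 965 higher and 1372 lower in knockout pools. Of these, 928 lay below the control level in both genotypes. After quantile normalization the split was 1154 higher and 1021 lower, and after median centring 1360 and 968. No probe set passed after Benjamini-Hochberg adjustment, either by the submitters' test (3907 at an unadjusted p under 0.05) or by limma without the trend (3606). With the trend limma called 70, 34 higher and 36 lower.

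Erythroid gene groups had medians between -0.19 and 0.13, where that of all genes was -0.08. Some probe sets were close to the ceiling, and single members differed in either direction. The median difference was 0.08 over 18 genes of heme synthesis and transport, -0.01 over 19 of iron uptake, -0.17 over 21 of the red cell membrane and -0.18 over 24 of organelle clearance and enucleation. No list of these was called by camera (adjusted p = 0.512, 0.949, 0.395 and 0.672). Fry's mixed test, which asks for change in either direction, called the red cell membrane list (adjusted p = 5.0e-07, the smallest of the 30 lists) and none of the other 3. Among members, Uros differed by 0.28 (0.16 without wild type replicate 2), Abcb10 by -0.38 (-0.13 without knockout replicate 3 and -0.20 without wild type replicate 3), Exoc6 by -0.40, the autophagy gene Gabarapl1 by 0.62 and Fbxo9 by -0.48. Within the membrane list, 18 of 21 members were lower in knockout, among them Epb42 (-0.39) and the glucose transporter gene Slc2a1 (-0.38), while Aqp1 rose. Only Aqp1 passed the threshold adjusted over that list alone, and the mixed test was not repeated without it. For every list the mixed test was run with the main settings only. Of the globins measured, Hbb-b2 differed by -0.16, with values from -0.28 to -0.041 without 1 array, and the embryonic gene Hbb-bh1 by -1.18 (SE 0.42). Hbb-y, at 83.7% to 97.7% of each array's highest signal, cannot show a change. Hba-a1 read 8.48 ± 0.34 and 7.16 ± 2.04, with the low value in knockout replicate 3 alone, and Hba-a2 lay below the control level in both genotypes, so these probe sets do not measure the abundant alpha globin transcripts. The median of the 3 adult globins was -0.16 and of the 3 embryonic globins -0.19 (camera adjusted p = 0.812 and 0.434), and with such members neither test informs on globin levels. The erythroid transcription factor list had a median of 0.13 (camera adjusted p = 0.212, fry mixed 0.0063), with Ldb1 at 0.87 (SE 0.29) and Cbfa2t3 at 0.50. Genes of immature progenitors moved both ways around a median of -0.03 (camera adjusted p = 0.353, higher by the test, fry mixed 0.0058). Myb, a transcription factor of proliferating progenitors, differed by 1.65 (SE 0.40), Myc by 1.10 (SE 0.23), Kit, the stem cell factor receptor gene, by 1.16 (SE 0.43) and Cd44 by 0.80 (SE 0.24). These 4 passed adjusted over the list alone with the mean-variance trend, with all knockout above all wild type arrays. Probe sets of Hbb-y, Cbfa2t3, Aurkb and Slc44a1 that lay above the control level in at least 1 genotype gave both directions.

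Camera with a preset correlation called 6 of the 30 lists, and none of them with an estimated correlation, where the smallest adjusted p was 0.839. Fry's mixed test called 9 lists, among them the cytokine-STAT5 list (adjusted p = 1.1e-04), the hypoxia list (0.0063) and the transcripts induced by handling (0.0360). Markers of hepatocytes, the other large cell population of the organ, were called lower in knockout pools (median -0.65, adjusted p = 2.7e-06, or 0.839 with an estimated correlation). The median was -0.98 without wild type replicate 3. All 19 were below 0, among them the fibrinogen gene Fgg (-1.07), the fetuin gene Ahsg (-1.11), Apoa1 (-0.73), Alb (-0.43) and Afp (-0.32). Alb read 15.79 ± 0.27 and 15.36 ± 0.11. Endothelial markers were called lower as well (median -0.52, adjusted p = 0.0015, or 0.839 with an estimated correlation). Lyve1 was at least 4.04-fold lower, while Kdr differed by 0.13 and Cdh5 by -0.14. The endothelial call ended without wild type replicate 3 (adjusted p = 0.0725) and with array weights (0.0701). Genes of cholesterol synthesis were called lower (median -0.31, adjusted p = 0.0342, or 0.839 with an estimated correlation), with all 19 below 0, among them Fdps (-0.97) and Idi1 (-0.68). That call ended without wild type replicate 2 (0.172) or 3 (0.0640) and without knockout replicate 1 (0.247) or 2 (0.190, median -0.20), and for the cholesterol list with array weights (0.0805). After median centring its median was -0.20. On the deposited scale its mean deviation from the wild type mean was -0.55 and -0.60 in knockout replicates 1 and 2. In knockout replicate 3 it was -0.008, inside the wild type range of -0.11 to 0.15.

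Transcripts that tissue handling is known to induce were called higher (median 0.31, adjusted p = 3.5e-04, or 0.839 with an estimated correlation). Of 21 members, 16 were above 0. The heat shock gene Hspa1a rose by 2.28 (SE 0.49), from 8.17 ± 0.37 to 10.45 ± 0.91. Members past the threshold adjusted over the list alone, with the trend, were Hspa1a, Hspa1b (2.16), Ier2 (1.11), Fos (1.01) and Dnajb1 (0.45), of which only Hspa1a passed over all genes tested. That call of Hspa1a ended whichever array was left out (adjusted p between 0.0674 and 0.156, limma with the trend). Signals of Hspa1a were 841.7, 1133.9 and 2841.3 in the 3 knockout pools and 311.9, 215.0 and 352.6 in wild type. Glycolysis genes were called higher (median 0.36, adjusted p = 0.0440, or 0.839 with an estimated correlation), with Hk2 at 0.84 and Aldoa at 0.44. So were hypoxia response genes (median 0.16, adjusted p = 0.0478, or 0.839 with an estimated correlation). Among them the histone demethylase gene Kdm3a rose by 1.06 and P4ha1 differed by 1.80. The other probe set of P4ha1 differed by 0.80. Without a knockout array that other probe set was the brighter and was used, with 0.89, 0.85 and 0.66 without knockout replicates 1, 2 and 3. The hypoxia median was 0.30 with the mean of all probe sets and 0.27 after median centring. The glycolysis list and the hypoxia response list lost the call after quantile normalization (adjusted p = 0.105 for each), with the low-value filter (0.0900 and 0.121) and with array weights (0.0701 for each). Without knockout replicate 3 the glycolysis list had a median of 0.14 (adjusted p = 0.273) and the hypoxia list one of 0.057 (0.398). Both also lost the call without knockout replicate 2 (0.0542 and 0.131) and without wild type replicate 1 (0.0809 for each, with a hypoxia median of 0.10), glycolysis without wild type replicate 2 (0.275, median 0.22) and hypoxia without wild type replicate 3 (0.135, median 0.079). Without wild type replicate 2 the hypoxia median was 0.26.

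**Figure D3:**
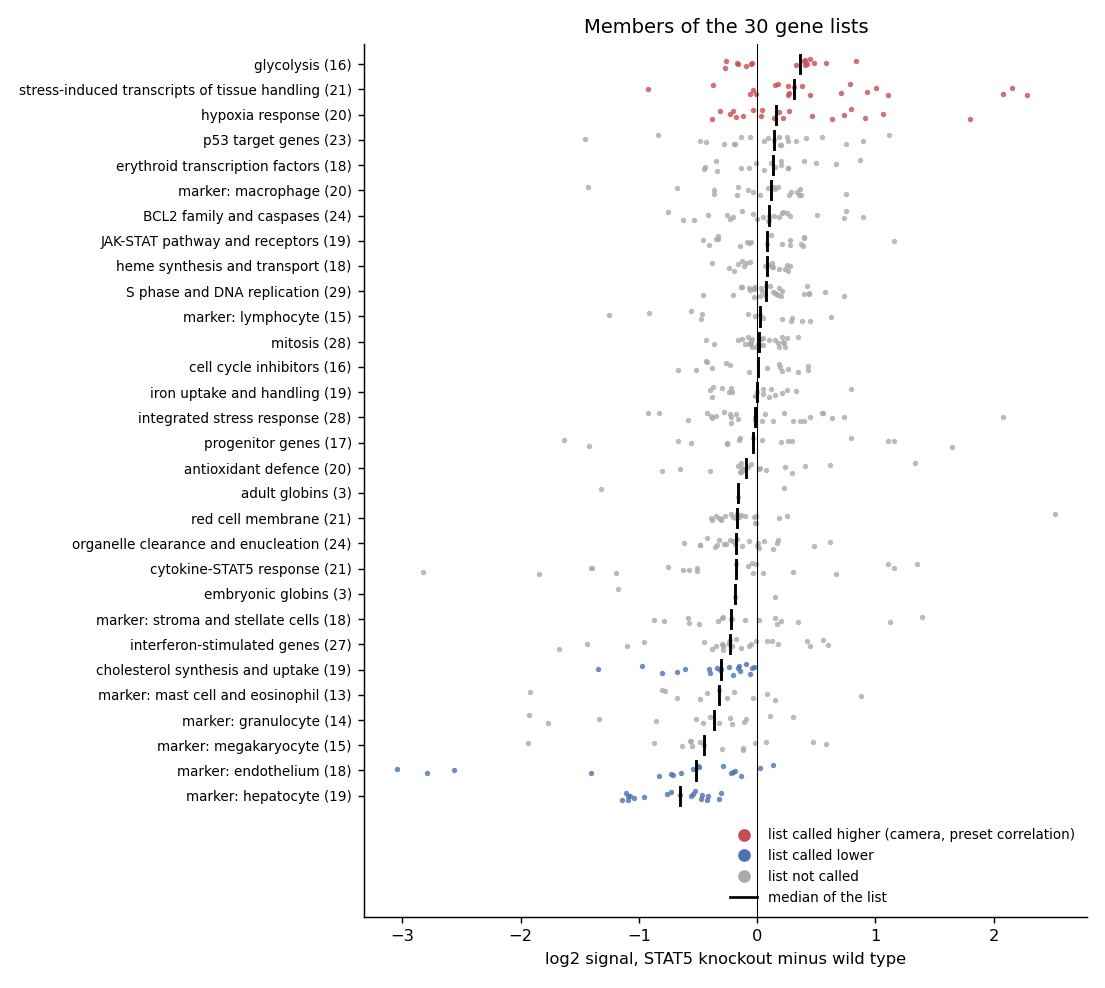
Difference in log2 signal, STAT5 knockout minus wild type (x axis), of each measured member (points) of the 30 gene lists (y axis, number of members in brackets), with black bars for list medians and colour for lists called by camera with a preset correlation. Medians run from -0.65 for hepatocyte markers to 0.36 for glycolysis.

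With the main settings camera called no other list of cell cycle, death or stress genes. Fry's mixed test called 3 of them, the BCL2 family and caspases (adjusted p = 0.0019), the integrated stress response (0.0044) and antioxidant genes (2.6e-06), each with members in both directions. By camera, the median was 0.07 for S phase (adjusted p = 0.0664), 0.02 for mitosis (0.395), 0.01 for cell cycle inhibitors (0.643), 0.10 for the BCL2 family and caspases (0.409) and 0.14 for p53 targets (0.266). Examples were the replication genes Pole (0.73) and Mcm6 (0.57), the mitotic genes Aurkb (-0.43) and Ube2c (-0.37), the inhibitor genes Cdkn1b (0.43) and Gadd45a (-0.38), and the pro-apoptotic gene Bbc3 (0.90). Trp53inp1, a p53 target, rose by 1.11 (SE 0.20) in the fit with the trend. The JAK-STAT list had a median of 0.09 (adjusted p = 0.414), with the receptor gene Csf2rb at -0.46. Interferon-stimulated genes had a median of -0.23 (0.395), with Rsad2 at -1.10. For the integrated stress response the median was -0.02 (0.684, higher by the test), with the enzyme genes Gpt2 at -0.83 and Mthfd2 at -0.92. Antioxidant genes had a median of -0.10 (0.949), a mean of 0.00 and both directions among members, with Gpx4 at -0.65. Gss, which makes glutathione, fell by 0.81 (SE 0.17) with the trend.

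Markers of other blood and support cells were not called by camera or fry without a block. Medians were 0.12 for macrophages (camera adjusted p = 0.395), -0.36 for granulocytes (0.168, or 0.0459 with the replicate number as a block), -0.45 for megakaryocytes (0.395), -0.32 for mast cells and eosinophils (0.395), 0.02 for lymphocytes (0.728) and -0.22 for stroma (0.949, higher by the test). Examples above the control level in wild type were Vcam1 (-0.68) for macrophages, Blnk (0.63, or 0.42 without knockout replicate 2) for lymphocytes and, for megakaryocytes, Ppbp, at 9.77 ± 1.93 against 7.83 ± 0.27. The Ppbp groups overlap, and its difference of -1.94 is -0.87 without wild type replicate 3. Knockout means under that level were at least 1.43-fold lower for Mmp8 of granulocytes, at least 1.24-fold for Epx of eosinophils and at least 1.23-fold for Selp of megakaryocytes. Among stroma genes Col5a1 rose by 1.13 (SE 0.18) with the trend, and Igfbp5 differed by -0.49. Chil3, Cd163, Mcpt8, Cd3g and Clec14a were dimmer than the control level in both genotypes, as was Ifi27l2a.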

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

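The tests on hepatocyte markers, on stress transcripts, on dim probe sets and on the neighbours of Stat5a were chosen only after the values they explain were seen. The tests on sex chromosomes and other splits of the arrays were set before their results were seen.

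The control probe set AFFX-LysX-5_at, for a Bacillus subtilis transcript and outside every comparison, was brighter in all 3 knockout arrays than in all 3 wild type arrays, by 2.04 on the log2 scale. Its signals were 2.3, 4.3 and 5.8 in wild type and 11.3, 38.4 and 9.0 in knockout, all far under the control level of 162.5. Of 64 control probe sets this was the only one with that order, where chance gives 3.2 one way. In the other direction 17 lay lower in knockout. Among them were the 3 for Tfrc, the 4 for pyruvate carboxylase, by -0.79 to -0.55, and several for Bacillus subtilis transcripts, by up to -2.66. The 95th percentile of the Bacillus subtilis controls was 172.8, 170 and 170.7 in the wild type arrays and 124.5, 163.6 and 143.2 in knockout. It was thus lower in every knockout array, and whether this enters the falls of dim genes was not tested.

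Hepatocyte markers were lower in the knockout pools. A candidate explanation is hepatocyte RNA carried over in amounts that vary between pools, which the Ter119 selection should remove. Within genotypes the 19 markers correlated at 0.718, above the 95th percentile of 0.172 for 1000 random lists of like brightness. Markers of 1 cell type can vary together whatever changes their amount, so this correlation does not favour carry-over over the explanations below. The markers' mean deviation in wild type pools ran from -0.49 to 0.51. In knockout pools it was nearly constant, at -0.75, -0.73 and -0.68, so the variation lies in the wild type pools. Alb and Afp, at 15.36 and 15.38 in knockout, were bright in every pool, at up to 91.0% and 90.2% of an array's highest signal, where differences may be compressed, so the carry-over would differ in amount and not in presence. A higher share of erythroid cells that dilutes all other types alike stays open: macrophage minus hepatocyte list means differed by 0.722 between genotypes, but overlapped (0.600 in wild type replicate 3, 0.538 in knockout replicate 1), and an effect of losing STAT5 on the liver stays open too, at an exact two-sided permutation p of 0.1, the smallest possible.

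Stress-induced transcripts were higher in the knockout pools. Camera's adjusted p was at most 8.8e-04 after quantile normalization and median centring (range over all alternatives 2.1e-05 to 0.839). Camera compares a list with all other genes, so a shift shared by all genes could hardly end the call. This p therefore decides little on the scaling of the arrays. The list median was 0.31 after quantile normalization and 0.42 after median centring, where that of all genes was -0.04 and 0.03. Within genotypes the transcripts correlated at 0.208, against a 95th percentile of 0.0589 for random lists. Transcripts that are induced together can correlate whatever induces them, so this value does not single out handling. The mean deviations of knockout pools were 0.27, 0.50 and 0.93. Handling that differed between single pools remains a candidate explanation. Loss of STAT5 remains another, with an exact permutation p of 0.1. Handling and genotype cannot be told apart with 3 pools each, since no label records the handling of a pool.

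The 80 genes called with a mean-variance trend were set against technical explanations. A different mix of male and female embryos in the pools is argued against as the source of most calls, since 5 of the 80 lie on the X chromosome and 0 on Y (upper 95% bound 14.0%, exact binomial). These are 6.25% of the calls, where 3.47% of the genes tested lie on X or Y. DNA flanking the Stat5 genes could come from the strain in which the knockout was made. As the source of most calls it is argued against only within the 100 genes nearest to Stat5a, which hold 0 of the 80. Few calls would fall among any 100 genes, so this 0 does not show that the flank is unchanged. Among these 100, knockout lay below wild type on all arrays for 17 and above for 4. A flank longer than these genes was not tested. Noise of dim probe sets could end calls once 32 is added to each linear value. Of the 13 genes with a genotype below the control level 12 kept the call, with a median of 0.735 of the difference left. These 12 calls thus do not rest only on the log of very low signals. The offset of 32 lies far under the control level of 162.5, so noise of the background stays open for them. Of the 13, 3 lay under that level in both genotypes. For the 67 genes above that level the test decides nothing, although 64 kept the call, since the offset leaves a median of 0.983 of their differences. Strain differences elsewhere in the genome were not tested and stay open, as does the loss of STAT5.

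With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The fit with the trend called 80 genes in the real split and at most 0 in any other, and the main test 8 and at most 1. Each of these counts was reached in 1 split of the 10, the real one. Probe sets past the submitters' criterion numbered 2337 against at most 1970, again reached in 1 split. The main test called 0 probe sets in all 10 splits. Camera called 6 lists in the real split and up to 10 in another, with 7 of the 10 splits at 6 or more. The fry directional test called 1 list in the real split and at most 1 in another, with 2 splits at that count.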

How the results depend on the processing

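No adjusted p of the 4 Stat5a and Stat5b probe sets passed 0.05 in any setting. Of the values of named genes under the alternatives, 1414 kept direction and side of the threshold, 71 passed it anew, 83 lost it and 12 turned sign. For lists these counts were 418, 16, 37 and 38, before the repeats of fry. Alternatives for the trend count and for fry were chosen after seeing the data. The cause was not tested for any change given here, except where fewer genes were tested or, as for P4ha1 and Dpys, another probe set was chosen. The ceiling limits the brightest probe sets, such as those of Alas2 and Hbb-y. Signal over background limits the results, since 31.6% of genes lay below the control level in both genotypes.

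The main count of 8 genes became 80 with the trend, 66 with robust and trend, 4 with the methods' t-test, 15 after quantile normalization, 3 after median centring, 20 with the low-value filter, 15 with array weights, 3 without suffixed probe sets, 18 at an adjusted p under 0.10 and 0 without any 1 array. For probe sets the count of 0 became 70, 69, 20 with the filter and 5 with the linear offset. The submitters' criterion gave 1156 with the filter, and 1997 to 2970 without 1 array. The 6 lists called became 4 after quantile normalization and 4 with the low-value filter, where glycolysis and hypoxia lost the call, 2 with array weights, 0 with an estimated correlation and 1 with fry, directional. The 80 genes called with the trend became 42 after median centring, 36 with the mean of all probe sets, and 9 to 75 without 1 array. The 1 list called by fry became 0 after median centring, and 0 to 1 without 1 array, where the list called without wild type replicate 1 was that of endothelial markers.

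Arrays of the same replicate number correlated between genotypes at 0.0230, 0.0414 and 0.0372 over all genes. Arrays of different numbers lay lower, between -0.0535 and 0.0187. The choice of all genes for this check was made after the count of genes called with the block had been seen, so the pairing stays open and the block is given beside the results it changes. Over the 11481 genes of the low-value filter each array again correlated best with its own number (0.113, 0.117 and 0.105). Both are a hint from the data and not from the design. With the replicate as a block the main test called 0 genes, the trend 75, camera 7 lists and fry 0 (adjusted p = 0.267 for the cytokine-STAT5 list).

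Signs turned after quantile normalization for Alas2 (0.031), mitosis (-0.035) and cell cycle inhibitors (-0.039), and after median centring for Ireb2 (0.092), Klf1 (0.10), iron uptake (0.11), progenitor genes (0.079), the integrated stress response (0.092) and antioxidant genes (0.017). They turned with the low-value filter for progenitor genes (0.044) and lymphocytes (-0.028), and with array weights for cell cycle inhibitors (-0.0078) and lymphocytes (-0.0057). With the mean of all probe sets they turned for progenitor genes (0.064), cell cycle inhibitors (-0.10), the integrated stress response (0.0071) and lymphocytes (-0.41), and without suffixed probe sets for Dpys (1.32). Without genes of several lists they turned for p53 targets (-0.058) and cell cycle inhibitors (-0.15).

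Without 1 array, values ran from -0.13 to 0.085 for Ireb2, -0.14 to 0.082 for Klf1 and -4.31 to 1.57 for Dpys. The positive values of Dpys, all without a wild type replicate, are those of another probe set, which was then the brightest (1.32 on all arrays). On all arrays that probe set lay below the control level in both genotypes. At the Dpys probe set used in the main test every knockout array lay below every wild type array. List medians ran from -0.059 to 0.12 for heme synthesis, -0.074 to 0.064 for cell cycle inhibitors, -0.10 to 0.27 for macrophages, -0.10 to 0.12 for progenitor genes, -0.11 to 0.21 for S phase, -0.12 to 0.13 for mitosis, -0.41 to 0.023 for stroma, -0.0064 to 0.11 for the JAK-STAT pathway, -0.088 to 0.012 for the integrated stress response, -0.20 to 0.10 for lymphocytes, -0.074 to 0.022 for iron uptake and -0.015 to 0.26 for p53 targets.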

Other observations

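The 7 genes called in the fit with a mean-variance trend whichever array was left out belong to several functions, and all were chosen after their values were seen. Cd36 and Socs3, lower in knockout, encode a fatty acid receptor and a cytokine signal inhibitor. Aqp1 and, at its brightest probe set, Slc44a1 were higher, and both encode membrane transporters. Dnaja4, lower, went from 12.67 ± 0.05 to 11.40 ± 0.03, while the heat shock genes Hspa1a and Hspa1b went the other way. Further single genes among the 80 calls, picked after their values were seen and not tested as groups, were Acsl5 (1.05), Plin3 (1.02), Rac2 (1.17) and Fermt3 (1.27), which rose. Plin3 lost the call with the replicate number as a block (adjusted p = 0.0902, limma with the trend) and whichever array was left out. Nars, which encodes the asparaginyl-tRNA synthetase of the cytoplasm, fell by 0.94.

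The test of the next hypothesis was chosen after its values were seen. Myc, Myb, Kit and Cd44 were higher in the knockout pools, and these genes are highest in early erythroid precursors. One hypothesis is a less mature mix of Ter119-positive cells. It would raise the progenitor list and lower the red cell membrane list, but camera called neither, at an adjusted p of 0.353 for progenitors and 0.395 for the membrane list. Of the 17 members of the progenitor list 9 were below 0, among them Cebpa (-0.67, overlapping groups), while Flt3 and Erg were too dim in knockout for a difference. The groups did not overlap for 5 members of that list, all higher in knockout pools. Of the 21 members of the membrane list 18 were below 0. There 6 members were lower without overlap of the groups and 1 was higher. Cd36 of early erythroblasts fell by 1.68, and Tfrc differed by -0.38. As early precursors of other lineages also carry Kit and Myb, these values decide nothing for or against it.

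Transcripts of sex-linked genes differed between pools. Xist, which female cells express, read 12.55, 11.98 and 9.23 in the 3 wild type pools and 12.47, 13.60 and 13.17 in the knockout pools. The Y-linked gene Eif2s3y read 7.08, 8.55 and 9.91 in wild type and 8.55, 5.28 and 4.22 in knockout. Kdm5d, also Y-linked, was nearly level at 7.26, 7.39 and 7.40 in wild type and 7.08, 7.77 and 7.44 in knockout. Uty read 8.31, 7.58 and 8.53 in wild type and 7.39, 6.91 and 6.70 in knockout. The lowest Eif2s3y and Uty values lie under the control level of 7.34, and Kdm5d stays close to that level in every pool, so its level values carry little information. In wild type replicate 3 Xist was lowest and Eif2s3y and Uty highest. In knockout replicates 2 and 3 Xist was highest and Eif2s3y and Uty lowest. Eif2s3y and Uty order the other pools differently.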
